A study of Homo sapiens with 2 samples.

How the data were processed

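Total RNA of U87 cells was extracted with silica columns, labelled with biotin and hybridised to arrays, per the labels' protocols. Cells were grown with 10% serum and treated in 1.5% serum for 72 h, with 10 µM ONC201 in the treated group and 0.1% DMSO in the control group. Each group had 1 array, and the group was taken from the treatment label of each sample. The treatment text of the DMSO sample also describes ONC201, as text shared by both samples.

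The deposited values are log2 levels, 1 per probe set, made with RMA in affy 1.36.1 under R 2.15.1, per the submitters' processing notes. RMA is known to subtract background, to give all arrays the same distribution of values, and to combine the probes of a probe set, and it tends to shrink large ratios and those of low levels. The array model and the genome build were not given in the sources used here. The log2 scale was checked on the deposited values, which ran from 0.834 to 12.5 with DMSO and from 0.834 to 12.4 with ONC201, with medians of 3.97 and 3.96. The sorted values of the 2 arrays differed with a standard deviation of 0.0193. A shared distribution removes any difference in total RNA per cell, so each difference is relative to the rest of the genes.

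The table held 23786 probe sets, each named by an Entrez Gene number, so each gene had 1 probe set. Through the platform annotation table, 22458 had 1 gene symbol, 0 had several and 1328 had none. Symbols and gene types were updated by Entrez Gene number with NCBI RefSeq on GRCh38.p14, of which no coordinates were used. Levels of different probe sets are not comparable as amounts of RNA, since probes differ in affinity.

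No further normalization was applied. The background level was the 95th percentile of the levels of 352 olfactory receptor genes, 3.12 log2, and a gene counted as expressed when the higher of its 2 values was above it. This kept 14533 genes, of which 12748 are protein-coding and 802 are long noncoding RNAs. The difference was the ONC201 value minus the DMSO value. Where the lower value was under the background level, the fold of a named gene was taken from the background level and is given as a lower bound, and where both were under it no fold is given. Counts of genes past a threshold and list medians use the measured differences, including those of genes with 1 value under the background level. Identical values in both arrays occurred in 1392 named genes, 408 of them expressed, and were kept.

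With 1 array per group there was no test of single genes. Gene lists, 39 with 971 entries, were written from textbook knowledge before the data were examined, and 874 entries were measured. For each list the median difference of its expressed members was set among 10000 random lists of the same size, drawn from the same 20 bins of mean level. A percentile of 2.5 or less, or of 97.5 or more, was described as standing apart. The list of mitochondrially encoded genes had 0 members named here. Some genes are in more than 1 list. Of the genes, the text names the 15 with the largest difference in each direction among expressed genes with 1 symbol (leaving out unnamed loci, small RNAs, pseudogenes and receptor segments), up to 4 members of each list by size of difference, and all members of the list of imipridone targets and signalling genes. Genes outside this rule are marked as named after their values were seen.

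The steps were tested on simulated data for the 14533 expressed genes, with random differences scaled to the median absolute deviation of the observed ones at each level. Of 100 genes seeded at 2 log2 in either direction 99 passed the 2-fold threshold, and of 100 seeded at 1.5 log2 96 did, while 68 unchanged genes passed it from noise alone. Of 4000 unshifted lists 216 (5.4%) stood apart, as did 94 of 100 lists of 20 genes shifted by 0.3 log2. These random differences were normal and independent between genes. The 5.4% therefore does not measure how often lists of genes that vary together would stand apart. The count of 68 rests on that normal shape and on no replicate arrays. It does not estimate how many of the observed 2-fold differences arose from noise. Alternatives were no filter on level, a filter at the median of all probe sets, both values above background, thresholds of 1.5-fold and 3-fold, removal of a loess trend on level (span 0.3), centring on the median, random lists not matched on level, the mean in place of the median, and lists without shared members, the last added after the data were seen. Intervals of list medians came from 10000 bootstrap resamples of a list's genes and describe the spread of those genes, not of cultures. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.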

Results

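Gene expression was measured on 2 oligonucleotide arrays of U87 cells, an established human glioblastoma line. One culture received 10 µM ONC201 (also called TIC10) and the other 0.1% DMSO, the solvent control, for 72 h in medium with 1.5% serum. ONC201 is an imipridone, a small molecule known to bind the mitochondrial protease ClpP and activate it, to antagonise the dopamine receptor DRD2, and to have been selected for induction of TRAIL, the product of TNFSF10. The comparison asks how the transcriptome of these glioma cells differed after ONC201. Each treatment had 1 array, so no difference has a replicate check, no p-value or standard error can be given, and the number of arrays limits the precision of every value. Differences are the ONC201 value minus the DMSO value of the deposited log2 levels, and a fold is that difference as a ratio. Among 14533 genes above the background level of 3.12 log2 in at least 1 array, the median difference was 0 with a standard deviation of 0.411. Pearson's r between the arrays, across those genes, which are not independent replicates, was 0.976, and Spearman's rho was 0.975. At least 2-fold differences were seen in 3.01% of these genes. Of 352 olfactory receptor genes, which set the background level, 23 were above it, and 1 of those lay at least 2-fold apart. Across all 352, 4 lay at least 2-fold apart (1.14%). The difference of these 352 genes had a standard deviation of 0.323, compared with 0.411 above, and their Pearson's r was 0.854. They were taken without a filter, at a median level of 1.95 log2, where RMA tends to shrink ratios. The other genes were kept by their higher value. The 0.323 is therefore not a measure of noise among the genes above background.

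At least 2-fold higher levels in the ONC201 array were found for 226 genes and at least 2-fold lower levels for 211. With both values above background these counts were 190 and 184. Among protein-coding genes, 8 were at least 8-fold higher and 0 at least 8-fold lower. CHAC1 (Entrez Gene 79094), which encodes a glutathione-degrading enzyme, had the largest difference, from 4.94 log2 with DMSO to 8.88 log2 with ONC201, or 15.4-fold. TRIB3, a stress-induced pseudokinase, was 11.6-fold higher, CTH, which makes cysteine from cystathionine, 10.7-fold, and the chemokine gene CXCL3 10.4-fold. The netrin receptor gene UNC5B was 9.08-fold higher, the stress gene SESN2 8.39-fold, the cytokine gene IL1A 8.33-fold and the glycine transporter gene SLC6A9 8.07-fold. Asparagine synthetase (ASNS) was 7.98-fold higher, ULBP1, a ligand of the natural killer cell receptor NKG2D, 7.68-fold, GDF15, a stress-induced secreted factor, 7.63-fold, and the cytokine receptor subunit gene IL20RB 7.43-fold. The long noncoding RNA LINC02806 was at background with DMSO, and its level with ONC201 was at least 5.43-fold higher.

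The genes with the largest downward differences included regulators of DNA replication and histone genes, beside others. FAM111B (Entrez Gene 374393), which encodes a serine protease, went from 8.44 log2 with DMSO to 5.98 log2 with ONC201, a 5.48-fold lower level. Cyclin E2 (CCNE2) was 4.63-fold lower, MCM10 3.998-fold, and CDC6 3.99-fold, the last of which loads the replicative helicase. ORC1, a subunit of the origin recognition complex, was 3.59-fold lower, the phosphatase gene CDC25A 3.55-fold, and the transcription factor genes E2F8 and MYBL1 3.87-fold and 3.46-fold. Among histone genes, H2AC13 was 3.90-fold lower, H3C8 3.68-fold and H2BC14 3.47-fold, while H1-1 was at background with ONC201 and at least 3.44-fold lower. Histone genes are near-identical copies, so the value of any single one is uncertain. The long noncoding RNA LINC01119 was 3.49-fold lower, LINC02913 at least 2.11-fold lower, and TCAF2, which has a close paralog, at least 4.35-fold lower.

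**Figure D1:**
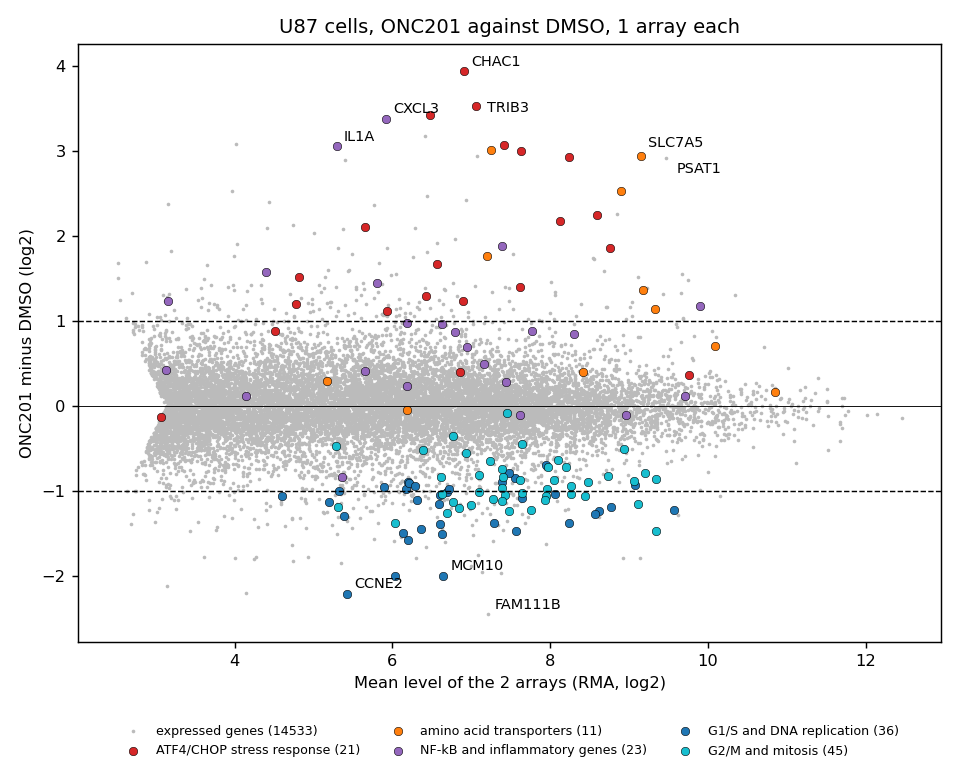
Difference of each of 14533 expressed genes (ONC201 minus DMSO, log2) against its mean level in the 2 arrays (RMA, log2), with members of 5 gene lists coloured and dashed lines at 2-fold. Members of the stress response and amino acid transporter lists lie up to 3.94 log2 above 0, and the members of both cell cycle lists all lie below 0.

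Genes of the ATF4/CHOP stress response, the transcriptional programme that follows phosphorylation of the initiation factor eIF2 alpha, were higher as a group. Of 21 measured members, 17 were at least 2-fold higher and 0 at least 2-fold lower. The median difference was 1.67 log2, above all of 10000 random lists of the same size and level (95% of which lay between -0.15 and 0.16). Beside CHAC1, TRIB3, CTH and SESN2, the genes of the transcription factors themselves were higher, DDIT3 (CHOP) 4.32-fold and ATF4 2.63-fold. Both were named after their values were seen. FGF21, likewise named afterwards and close to background in both arrays, was the 1 member below 0, at -0.13 log2.

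Genes that supply amino acids and charge transfer RNAs, many of them known ATF4 targets, were higher too. Of 11 amino acid transporter genes, 6 were at least 2-fold higher, with a median of 1.14 log2. They included SLC7A5, the leucine transporter, at 7.70-fold, SLC7A11, the cystine transporter, at 5.79-fold, and SLC1A4 at 3.40-fold. Of 12 genes of serine and one-carbon synthesis, 5 were at least 2-fold higher. Their median was 0.84 log2 (bootstrap interval -0.373 to 1.61 log2). PSAT1 was 7.54-fold higher, the mitochondrial folate enzyme genes ALDH1L2 and MTHFD2 5.39-fold and 3.32-fold, and PHGDH, the first enzyme of serine synthesis, 2.80-fold. That list was not uniform, as 2 members, ALDH18A1 at -0.73 log2 and SFXN1 at -0.66 log2, were at least 1.5-fold lower. Both were named after their values were seen. All 12 cytosolic tRNA synthetase genes listed as ATF4-dependent were higher, by 0.55 log2 or more, with a median of 1.13 log2. WARS1 was 4.79-fold higher, AARS1 2.94-fold, MARS1 2.86-fold and CARS1 2.48-fold. The 7 other cytosolic synthetase genes had a median of -0.09 log2 (percentile 26), and 0 of them were 1.5-fold apart. Their highest value was that of VARS1 at 0.15 log2 and their lowest that of FARSB at -0.29 log2. The transporter, serine and ATF4-dependent synthetase lists, like the ATF4/CHOP list, lay above all of their random lists.

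**Figure D2:**
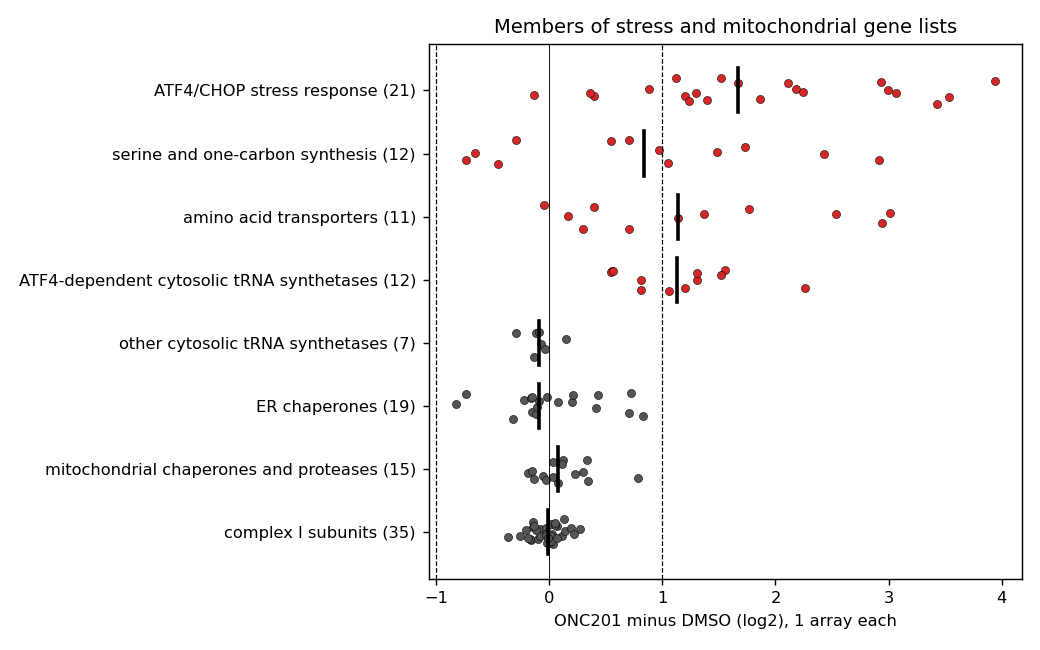
Difference (ONC201 minus DMSO, log2) of each expressed member of 8 gene lists, 1 point per gene, with a black bar at the list's median and dashed lines at 2-fold. The 4 lists in red have medians from 0.84 to 1.67 log2, and the 4 lists in grey have medians between -0.09 and 0.08 log2.

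Genes of endoplasmic reticulum chaperones and protein degradation did not move as a group. Of 19 members, 3 were at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of -0.09 log2 (percentile 14.5). HERPUD1 was 1.77-fold and EDEM1 1.65-fold higher, while MANF was 1.77-fold and SDF2L1 1.66-fold lower. XBP1 had a difference of 0.71 log2, and HSPA5, the main chaperone of that compartment, 0.21 log2, both named after their values were seen.

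Among 15 mitochondrial chaperone and protease genes, LONP1, a matrix protease, was 1.72-fold higher, and the other 14 lay within 1.5-fold. The list's median was 0.08 log2 (percentile 85.6). DNAJA3 had a difference of 0.35 log2, HSPA9 of 0.33 log2 and OMA1 of 0.30 log2. All 35 nuclear genes of complex I subunits lay within 1.5-fold, from NDUFA6 at -0.36 log2 to NDUFA3 at 0.28 log2, with a percentile of 51.3. All 32 subunit genes of complexes II to V did too, with a median of -0.11 log2 (percentile 4.33), SDHD lowest at -0.43 log2 and UQCRB highest at 0.32 log2. With no filter on low levels that list passed the threshold for lower (percentile 1.10). The 74 genes of mitochondrial ribosomal proteins had a median of -0.09 log2 (bootstrap interval -0.158 to 0.0176 log2). Its percentile of 2.04 was just past the threshold for lower. That call ended when the mean replaced the median (percentile 6.39). MRPS18C was 1.84-fold lower, the 1 member at least 1.5-fold apart, followed by MRPL48 at -0.55 log2. Of 18 genes of mitochondrial DNA maintenance and transcription, NRF1 was 1.60-fold lower and TFAM, the DNA packaging factor, 1.41-fold, with a median of -0.08 log2 (percentile 16.9). Genes encoded on mitochondrial DNA were not analysed here.

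Genes of cell division were lower throughout. All 36 genes of G1/S transition and DNA replication were at least 1.5-fold lower, 24 of them at least 2-fold, with a median of -1.12 log2. CHAF1A, a subunit of the complex that places histones on replicated DNA, was 2.99-fold lower. Of 45 genes of G2/M and mitosis, 38 were at least 1.5-fold lower and 20 at least 2-fold lower, and the median was -0.95 log2. The cytokinesis gene ANLN was 2.76-fold lower, the spindle motor genes KIF15 and KIF11 2.60-fold and 2.35-fold, and the checkpoint kinase gene TTK 2.39-fold. Both medians lay below all of their random lists. Ribosome biogenesis and MYC target genes had a smaller shift, with a median of -0.18 log2 (percentile 0.26), in which 2 of 30 members were at least 1.5-fold lower. TCOF1 was 1.68-fold and LYAR 1.51-fold lower. Cytosolic ribosomal protein genes did not stand apart, with a median of -0.03 log2 over 43 genes (percentile 32.3), and RPL32 had the largest difference at 0.67 log2.

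Inflammatory genes were higher. Of 23 members of the list of NF-kB and inflammatory genes, 13 were at least 1.5-fold higher, 7 of them at least 2-fold, and 1 was at least 1.5-fold lower (IL11 at -0.83 log2, named after its value was seen). The median was 0.85 log2, above all random lists. With CXCL3 and IL1A, IL6 was 3.68-fold higher and CXCL1 2.98-fold. CXCL1, CXCL2 and CXCL3 are similar in sequence, so their separate values are uncertain. Interferon-stimulated genes had a smaller median of 0.29 log2 (percentile 99.95) and were mixed. Of 25 members, 5 were at least 1.5-fold higher and 2 at least 1.5-fold lower. XAF1 was 2.61-fold and the transcription factor gene IRF1 2.30-fold higher, whereas the antiviral synthetase family genes OASL and OAS3 were 1.71-fold and 1.60-fold lower. Of 17 immune cell markers 8 were above background, with a median of -0.07 log2 (percentile 34.5), and none was 1.5-fold apart. ITGAX was at least 1.35-fold higher and CD79A had a difference of -0.37 log2.

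Genes of the compound's known targets and signalling are given whatever their values, and those of the cell death lists by size of difference. TNFSF10, which encodes TRAIL, was below background in both arrays (2.43 log2 with DMSO and 2.49 log2 with ONC201), as was FOXO1 (2.56 and 2.87 log2), so neither has a fold. Among TRAIL receptor genes, TNFRSF10B (DR5) was 1.88-fold higher, TNFRSF10C 2.28-fold higher and TNFRSF10D 1.87-fold lower. TNFRSF10A (DR4), named after its value was seen, was above background with DMSO alone. Its measured difference of -0.39 log2 rests on an ONC201 value under background. The death receptor list as a whole had a median of 0.05 log2 (percentile 72.4) over 14 members, of which 10 lay within 1.5-fold. CASP10 was at least 1.75-fold higher. The BCL2 family had a median of 0.06 log2 (percentile 75.4) over 16 members. Its pro-apoptotic members PMAIP1 and BCL2L11 were 1.91-fold and 1.83-fold higher, the pro-apoptotic HRK was 1.70-fold lower, and the anti-apoptotic BCL2L2 was 1.50-fold higher. The 19 expressed genes of the imipridone target and signalling list had a median of -0.10 log2 (percentile 16.1). CLPP and CLPX, the protease and its partner, had differences of 0.04 and 0.12 log2. AKT1 had a difference of 0.05 log2, AKT2 of -0.13 log2, MAPK3 of 0.03 log2 and MYC of -0.26 log2. FOXO3 was 1.70-fold lower. Of the eIF2 alpha kinases, EIF2AK3 was 1.56-fold lower, EIF2AK1 had a difference of -0.11 log2, EIF2AK4 of 0.03 log2 and EIF2AK2 of 0, and DELE1, a mitochondrial stress relay, had 0.12 log2. Dopamine receptor genes were close to background, DRD5 at 3.73 log2 with DMSO and 3.63 log2 with ONC201. DRD2 was at 3.20 log2 with DMSO and below background, at 3.09 log2, with ONC201. DRD1, DRD3 and DRD4 were likewise above background with DMSO alone, at 3.22, 3.29 and 3.49 log2.

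Targets of p53 had a median of 0.28 log2 over 23 members (percentile 99.96), of which 4 were at least 1.5-fold higher and 0 lower. These were GDF15, GADD45A at 2.61-fold, TNFRSF10B, and TIGAR at 1.58-fold. GDF15 is also in the ATF4/CHOP list, GADD45A in the FOXO list, and TNFRSF10B in the death receptor and imipridone lists. CDKN1A, named after its value was seen, was 1.27-fold higher. FOXO-induced genes had a median of 0.23 log2 over 17 members (percentile 99.6, bootstrap interval -0.0554 to 0.691 log2). Of these, 6 were at least 1.5-fold higher and 1 lower. FBXO32 was 1.72-fold and CCNG2 1.62-fold higher. This call ended without the members shared with other lists (percentile 87.8), an alternative chosen after the data were seen. Genes that respond to ERK signalling had a median of -0.25 log2 over 27 members (percentile 0.03). Of these, 4 were at least 1.5-fold lower and 23 lay within 1.5-fold, and 6 were above 0. EPHA2 was 2.13-fold lower, JUN 1.67-fold and SPRY4, a feedback inhibitor, 1.60-fold, and SPRY1, at background with ONC201, at least 1.14-fold.

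Antioxidant genes under NRF2 were higher, with a median of 0.42 log2 over 19 members, above all random lists. Of these, 8 were at least 1.5-fold higher and 0 lower. With SLC7A11, GCLC, which makes the first step of glutathione synthesis, was 2.53-fold higher, SRXN1 2.20-fold and heme oxygenase 1 (HMOX1) 2.05-fold. Autophagy and lysosome genes had a median of 0.18 log2 over 25 members (percentile 99.8, bootstrap interval 0 to 0.251 log2). MAP1LC3B was 1.77-fold, ULK1 1.69-fold and HEXA 1.51-fold higher. Cytosolic heat shock protein genes were lower, with a median of -0.33 log2 over 14 members (percentile 0.01), of which 2 were at least 1.5-fold lower and 0 higher. HSPA1A and HSPA1B, which are near-identical copies, were 2.01-fold and 1.59-fold lower. The 7 metallothionein genes had a median of -0.09 log2 (percentile 27.3), with MT1G at 0.53 log2 and MT1X at -0.47 log2.

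Among metabolic lists, cholesterol synthesis and glycolysis were lower. Cholesterol synthesis genes had a median of -0.40 log2 over 19 members, below all random lists. HMGCS1, an early enzyme of the pathway, was 2.07-fold lower, EBP 1.62-fold, SQLE 1.49-fold and IDI1 1.48-fold. Glycolysis genes had a median of -0.25 log2 over 19 members (percentile 0.09). The 4 at least 1.5-fold lower were PFKFB4 at -0.998 log2, PFKFB3 at 1.94-fold, both of which set fructose 2,6-bisphosphate, and the isoenzymes ALDOC and ENO2 at 1.94-fold and 1.62-fold. Hypoxia-induced genes had a median of -0.12 log2 over 18 members (percentile 6.89), with MXI1 1.58-fold higher and P4HA1 and BNIP3 both 1.55-fold lower. The list passed the threshold for lower with the mean in place of the median (percentile 1.92). The tricarboxylic acid cycle list (15 genes, median -0.15 log2, percentile 5.19) and the fatty acid synthesis list (11 genes, median -0.06 log2, percentile 32.6) did not stand apart. IDH2 had the largest difference of the former at -0.43 log2 and FASN of the latter at -0.26 log2.

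Extracellular matrix and mesenchymal genes did not stand apart as a group, with a median of -0.05 log2 over 39 members (percentile 27). Still, THBS1 was 2.47-fold, CCN2 2.29-fold and the protease gene PLAU 1.62-fold lower. Glioma and neural progenitor markers had a median of -0.15 log2 over 14 expressed members of 22 measured (percentile 5.61). NES (nestin) had a difference of -0.43 log2. OLIG2 had a difference of 0.55 log2 but was close to background, at 3.35 log2 with DMSO and 3.90 log2 with ONC201. The 8 expressed neuron and oligodendrocyte markers had a median of -0.37 log2 (percentile 0.54, bootstrap interval -0.697 to 0.301 log2). SNAP25 was 1.93-fold lower and MAP2 1.71-fold higher. Without the filter on low levels that list's percentile was 53.99, and its call ended. Of markers of other cell types, the 8 epithelial ones had a median of -0.07 log2 (percentile 39.4) and the 6 endothelial ones -0.01 log2 (percentile 53.5). KRT19, close to background at 3.28 log2 with DMSO and 3.88 log2 with ONC201, was 1.51-fold higher. KDR had a difference of -0.39 log2.

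**Figure D3:**
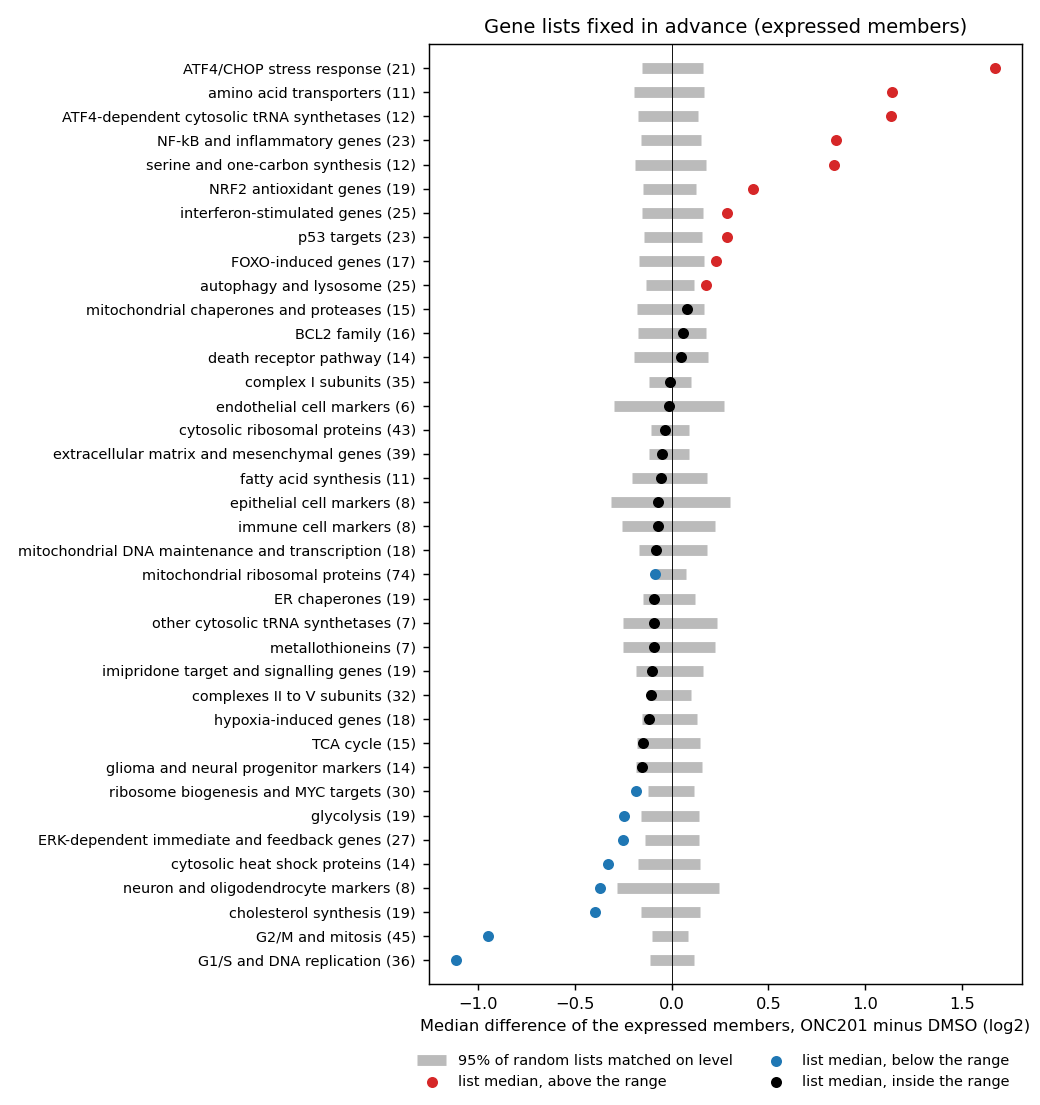
Median difference (ONC201 minus DMSO, log2) of the expressed members of each of 38 gene lists, with grey bars for the middle 95% of 10000 random lists matched on level and the number of members in brackets. Of the lists, 10 lie above their bar, from autophagy at 0.18 to the ATF4/CHOP list at 1.67 log2, 9 lie below it, and 19 lie inside.

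Of 38 lists with a percentile, 10 stood apart as higher and 9 as lower. Lists of unrelated genes would give 1.9 by chance. Genes of a list can vary together and some lists share members, so the comparison with 1.9 does not exclude chance. Among the lists that stood apart, bootstrap intervals spanned both signs for serine synthesis, FOXO-induced genes, mitochondrial ribosomal proteins and neuron markers. The interval of autophagy genes began at 0, and those of the other lists that stood apart kept the sign of their medians. A percentile describes these 2 arrays and does not carry to other cultures.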

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

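Among probe sets with no gene symbol here, which entered no comparison, 757 were above the background level, and 10 of these were at least 2-fold higher in the ONC201 array than in the control. That is 1.32% of them, compared with 1.56% of named expressed genes. Another 13 were at least 2-fold lower, and the extreme differences were 1.98 and -2.31 log2. With 1 array per treatment no sample could be compared with others of its group. No explanation was tested for these probe sets.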

How the results depend on the processing

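Counts of genes at least 2-fold apart stayed within 1.5 times of 226 higher and 211 lower with no filter, the stricter filters, removal of a loess trend and centring, and by definition moved with the threshold, to 854 and 821 at 1.5-fold and to 56 and 26 at 3-fold. Pearson's r across genes was 0.988 with no filter and 0.966 with the filter at the median level, and the standard deviation of the difference 0.367 and 0.424. Centring moved nothing, since the median difference was already 0. Of 247 alternative list percentiles, 239 stayed on the same side of the threshold. The exceptions lay in 5 lists, and their cause was not tested. Mitochondrial ribosomal proteins no longer stood apart with the filter at the median level (percentile 2.57), with random lists not matched on level (3.36) or with the mean (6.39). Neuron and oligodendrocyte markers went to percentile 53.99 with no filter, which adds members at background, and to 5.25 with the mean. Complexes II to V came to stand apart as lower with no filter (1.10), and hypoxia-induced genes with the mean (1.92). FOXO-induced genes went to 87.8 without members of other lists, a test chosen after the data were seen. Of 177 named genes with a loess value, 2 changed side of 2-fold, PFKFB4 and HSPA1A, and no move passed 0.0683 log2. No paired analysis was possible because each treatment had 1 array and the labels give no replicate numbers, and for the same reason no replicate could be left out. The choice between several probe sets of a gene was not run, as each gene had 1. Signal over background limits the genes at background in 1 array, whose folds are lower bounds.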

Other observations

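Further gene groups were picked after the differences had been seen, so their percentiles describe them and are not independent evidence. Some members of the kinetochore, glutathione, vacuolar ATPase and YAP/TEAD groups are also in the lists fixed beforehand. Those members are not new observations. Of 36 expressed replication-dependent histone genes, 29 were at least 1.5-fold lower and 17 at least 2-fold lower in the ONC201 array, with a median of -0.97 log2. H2BC18 was the 1 member at least 1.5-fold higher, at 0.82 log2, and these near-identical genes cannot be read singly. Of 21 genes of the Fanconi pathway and homologous recombination, 14 were at least 1.5-fold lower, with a median of -0.83 log2. BRIP1 was 2.95-fold lower and BRCA1 1.78-fold. Centromere and kinetochore genes had a median of -0.93 log2, and 20 of 27 were at least 1.5-fold lower, with CENPI 2.61-fold. Nuclear pore genes were shifted less, with a median of -0.35 log2 over 25 members and 5 at least 1.5-fold lower. These 4 medians lay below all of 10000 random lists matched on level. LMNB1, the gene of lamin B1, which is in none of the lists and was named after its value was seen, was 3.03-fold lower.

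Of 14 genes of transsulfuration and glutathione handling, 8 lay within 1.5-fold. CHAC1, CTH, SLC7A11, CBS (5.15-fold) and GCLC were at least 2-fold higher, and CHAC2 was lower at -0.72 log2, the 1 member at least 1.5-fold lower. The list's median was 0.22 log2 (percentile 99.4) and its mean 1.001 log2. Of 6 expressed NKG2D ligand genes ULBP1 alone was 1.5-fold apart, and the list's median was -0.04 log2 (percentile 39.98). Of 17 vacuolar ATPase genes ATP6V0D2 alone was 1.5-fold apart, at 2.09 log2, with a list median of 0.07 log2 (percentile 87.7). YAP/TEAD target genes had a median of -0.25 log2 over 21 members (percentile 0.07), with a bootstrap interval that spanned both signs (-0.373 to 0.123 log2). THBS1 and CCN2 were at least 2-fold lower, and IGFBP3 was 2.14-fold higher. PCK2, a mitochondrial enzyme that makes phosphoenolpyruvate, is in none of the lists and was named after its value was seen. It was 3.65-fold higher.

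Of the tests on the following 3 patterns, those on members near background (inflammatory genes) and on the level trend (cell cycle genes) were chosen before their results were seen, and all the others after.

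The ATF4/CHOP list was higher in the ONC201 array, by a median of 1.67 log2. A trend of the difference with level was too small to account for this, since the medians of 10 equal groups of genes by level were at most 0.0593 log2 from 0. RMA gives both arrays nearly the same distribution, which leaves little room for such a trend. A large one was therefore unlikely in advance. An unfolded protein response of the endoplasmic reticulum stays open. The 95% bootstrap interval of the median of that compartment's chaperones ended at 0.208 log2, but members went both ways, with HERPUD1, EDEM1 and XBP1 at least 1.5-fold higher and MANF and SDF2L1 at least 1.5-fold lower. With 1 array per treatment, cultures or arrays that differ in something other than the compound cannot be told apart from it.

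The inflammatory list was higher by a median of 0.85 log2. Immune cells in the treated culture would bring their abundant transcripts, yet PTPRC, LYZ and CD14 were all below the background level of 3.12 log2 in the ONC201 array, the highest at 2.09 log2. Of the 17 immune markers 8 were above background, among them CSF1R, at 4.53 log2 with DMSO and 4.28 log2 with ONC201, and ITGAX, at 2.98 and 3.56 log2. PTPRC, LYZ and CD14 were chosen from these markers after the values were seen, so they do not exclude immune cells. Members near background were not the source of the shift. The 19 members above the median level of all probe sets in both arrays had a median of 0.697 log2, above all of their random lists. A response of the glioma cells to ONC201 may explain the pattern, but with 1 array per treatment it cannot be told apart from another difference between cultures or arrays.

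The cell cycle lists were lower, by medians of -1.12 and -0.95 log2. A trend of the difference with level did not account for this, since after its removal the less negative of both medians was -0.932 log2, below all random lists. The shared distribution that RMA gives left little trend to remove. A smaller share of dividing cells with ONC201 may account for the pattern, as may a difference in density between cultures. With 1 array per treatment these cannot be told apart.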
